A study of Homo sapiens with 4 samples.

How the data were processed

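RNA was measured in 4 samples of a cell line labelled SH-SY5Y, 2 wild type and 2 with TDP-43 knocked down with CRISPR, grown in DMEM with serum. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was depleted and stranded libraries were made. The authors deposited 1 table of whole-number counts per gene, with 60669 versioned Ensembl gene identifiers and 1 column per sample. Per the submitters' processing notes, FastQC, STAR, featureCounts and edgeR were used with the genome build GRCh38. Their versions, the annotation release, the strand setting and the treatment of reads that match several places or several genes are not given in the sources used here. The counts were used as deposited.

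The table itself shows that some reads were counted in more than 1 gene. Among 10495 rows with at least 200 counts, 10 have the same 4 counts as another row, among them RN7SK, RMRP and SCARNA2. The 22 tested genes of the protocadherin gamma cluster, which share their last exons, have mean counts of 527 to 960.2, with a median of 534. Values of overlapping genes and of near-identical copies are therefore uncertain. Gene symbols came from a gene name table that matched 60370 of the identifiers with version ignored, and coordinates from GENCODE 29 (GRCh38), which holds 58482 of them, 40342 with the same version.

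Depth differed between libraries. Wild-type replicate 1 had 1962476 counts and 19792 genes with a count, replicate 2 had 5830845 and 23704, knockdown replicate 1 had 7815766 and 24727, and knockdown replicate 2 had 8081765 and 24796. A floor of 3 counts equals 1.53, 0.515, 0.384 and 0.371 CPM in these libraries in that order, and 0.385 CPM over the wild-type and 0.189 CPM over the knockdown pair. Counting intervals and floors cover counting error only. SEs were derived from the log2 fold change and the edgeR test statistic, which takes in the spread between libraries. The interval of RIGI was taken from its SE by a normal approximation. The 2 libraries of a group differed by more than sampling noise, with a chi-square per degree of freedom of 6.04 in wild type and 5.40 in knockdown over genes with at least 50 counts, which argues against a repeated deposit of 1 library but does not show separate cultures. Log2 CPM correlated at 0.961 within wild type and 0.987 within knockdown across genes, which are not independent replicates.

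Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the group and its minimum count of 10, which left 15977 of 28797 genes with a count. Libraries were scaled by TMM, with factors of 0.969, 1.02, 0.997 and 1.01, dispersions were estimated (biological coefficient of variation 0.0762), and knockdown was compared with wild type by the robust quasi-likelihood test with Benjamini-Hochberg adjustment and a threshold of 0.05. Means and SDs are of TMM-scaled CPM. An exact permutation of 2 against 2 libraries cannot give a two-sided p below 0.333, so tests rest on the gene-wide model. Of the 39 gene lists fixed before the data were examined, 36 had at least 5 tested members and were compared with all other genes by camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 36 lists. camera with an estimated correlation and fry were run beside it. Genes counted over the list alone were adjusted over its tested members.

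The genes named in the text follow a rule written before the data were examined. It takes 22 fixed genes, the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 5 CPM and no overlap between groups, the 5 smallest p-values, and up to 4 genes per list with the smallest p. List members named because they went against their list or did not pass, the genes of the kidney panel, the tRNA synthetases and the protocadherins were chosen after their values were seen. Genes below the filter are given as pooled counts, and a ratio with 1 to 3 counts in a group has an exact binomial interval. Some genes and 1 tested list that the rule takes are not reported here.

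The test was tried on simulated data drawn from the real means, dispersions and library sizes over 15977 genes, with 200 genes changed. edgeR recovered 20% of the 50 genes changed 1.5-fold, 52% of the 50 changed 2-fold, 88% of the 50 changed 4-fold and 94% of the 50 changed 8-fold, and it called 7 of 15777 unchanged genes. camera called a list of 30 genes raised 1.5-fold and none of 50 unchanged lists. Genes were drawn independently and lists at random, so the trial says nothing about lists whose genes move together. With 200 genes changed against 6019 called in the data, the recovery rates may not carry over. Alternatives planned beforehand were a replicate block, DESeq2 1.42.0, limma-voom, other size factors, other filters, a non-robust fit, leaving out abundant noncoding RNA, a test against a 1.5-fold change, leaving out each library, and other list tests. Thinning to equal depth, leaving out repeated rows and correcting the members of 2 lists were added after seeing the data.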

Results

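The series measured RNA levels in a human cell line labelled SH-SY5Y, a line that was derived from a neuroblastoma, a childhood tumour of the sympathetic nervous system. Libraries of ribosomal RNA-depleted total RNA came from 2 wild-type samples and from 2 samples in which TDP-43 was knocked down with CRISPR. TDP-43, the product of TARDBP, is a nuclear RNA-binding protein that regulates splicing. The series title places it between the cell's own RNAs and an interferon response through RIG-I, a sensor of double-stranded RNA. The comparison of knockdown with wild type shows whether interferon-related transcripts differ. It cannot show a route through RIG-I, since the labels name no sample without RIG-I. Counts assigned to genes totalled 1962476 and 5830845 in wild-type replicates 1 and 2, and 7815766 and 8081765 in knockdown replicates 1 and 2. In what follows, levels are CPM, counts scaled to each library's total with its TMM factor, with the SD over n = 2 libraries per group, and fold changes are knockdown over wild type on the log2 scale. Nothing in the labels says that the replicates were separate cultures, so the p-values measure only the spread between these libraries.

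TARDBP (ENSG00000120948.18, chromosome 1, 11012344 to 11026420 in GRCh38), the targeted gene, was lower in both knockdown libraries. It had 178 and 522 counts in the wild-type libraries and 174 and 189 counts in the deeper knockdown libraries. Its level fell from 91.0 ± 4.15 to 22.8 ± 0.518 CPM, a 3.96-fold decrease (log2 fold change -1.99, SE 0.128, edgeR adjusted p = 8.49e-12).

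Transcripts of 6019 genes changed in knockdown, with CDH6, TGM2, OAS2 and IFI6 among the 5 smallest p-values. TGM2, a protein-crosslinking transglutaminase, rose from 40.5 ± 5.75 to 789.7 ± 0.0565 CPM. ANGPTL4, a secreted inhibitor of lipoprotein lipase, rose from 2.16 ± 0.673 to 189 ± 6.94 CPM, and IFITM1, an antiviral membrane protein, rose from 1.72 ± 0.193 to 138 ± 7.16 CPM. CDH6, a cadherin, fell from 502 ± 41.2 to 17.0 ± 2.50 CPM, and CD24, a glycosylated surface protein, fell from 1318 ± 116 to 52.4 ± 11.6 CPM. VAV3, a guanine nucleotide exchange factor, fell from 39.5 ± 4.58 to 1.11 ± 1.03 CPM, ADAMTS5, a matrix protease, fell from 64.7 ± 1.06 to 3.47 ± 1.10 CPM, and ANK3, a membrane scaffold, fell from 12.2 ± 0.127 to 0.696 ± 0.291 CPM. The log2 fold changes were 4.23 for TGM2, 6.60 for ANGPTL4, 6.25 for IFITM1, -4.89 for CDH6, -4.65 for CD24, -5.08 for VAV3, -4.21 for ADAMTS5 and -4.11 for ANK3. FLRT1 had no count in wild type and 301 counts in knockdown, a pooled level 49.2 times a floor of 3 counts over the wild-type libraries. CEACAM1 had 2 wild-type and 453 knockdown counts, a depth-scaled ratio of 111 (95% counting interval 30.6 to 920), and NLRP3, the sensor of an inflammasome, had 3 and 266, a ratio of 43.5 (14.7 to 212). KLHDC7B had 1 and 166, a ratio of 81.4 (14.4 to 3230). In the other direction, DUX4L51 had 112 wild-type and 3 knockdown counts, a ratio of 76.2 (25.4 to 375) in favour of wild type, but this pseudogene lies within CDH6 on the same strand and has near-identical copies, so its counts cannot be separated from the fall of CDH6. TMEM37, UNC13C, SLCO4C1 and CCDC183 also fell by 18.3-fold or more, and RASGRP3, ISG20 and MX2 rose by 35.5-fold or more. PDCD1LG2, an inhibitory ligand of T cells, rose from 4 to 396 counts, a ratio of 48.5 (18.8 to 179). Of 15977 genes tested with edgeR, 3066 rose and 2953 fell, together 37.7%. At least 2-fold rises numbered 1261 and falls 1016. DESeq2 called fewer, 1953 higher and 1876 lower, and without knockdown replicate 1 or 2 edgeR called 1920 or 1930 lower. Each fit without 1 library left 1 library in a group, so the other group alone gave the spread. The same holds without wild-type replicate 1, which had the fewest counts, so that fit does not settle its influence.

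Interferon-stimulated genes had the highest median log2 fold change of the 36 lists tested. ISG15, a ubiquitin-like modifier, rose from 50.9 ± 6.38 to 522 ± 20.4 CPM, and IFIT1, which binds foreign 5' ends of RNA, rose from 82.6 ± 8.53 to 490.5 ± 44.0 CPM. OAS2, an activator of RNase L, rose from 35.2 ± 2.74 to 449.6 ± 0.193 CPM, IFI6 from 51.9 ± 1.03 to 522 ± 9.05 CPM and MX2, a GTPase that restricts viruses, from 9.66 ± 5.44 to 432 ± 18.6 CPM. IFIT2 (2.14), IFIT3 (2.89), MX1 (2.40) and OAS1 (2.70) rose on the log2 scale as well. Of the 71 tested genes, 67 rose and 2 fell (67 and 2 adjusted over the list alone), 65 and 1 with DESeq2, with a median log2 fold change of 1.99. SHISA5 was among those that fell, and TRIM5 and GBP2 did not pass, all named after their values were seen. limma's camera, which compares a list with all other genes, gave an adjusted p of 8.09e-29 for the list. The call was lost with an adjusted p = 0.401 with an estimated correlation, for which the 4 libraries leave 2 residual degrees of freedom.

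**Figure D1:**
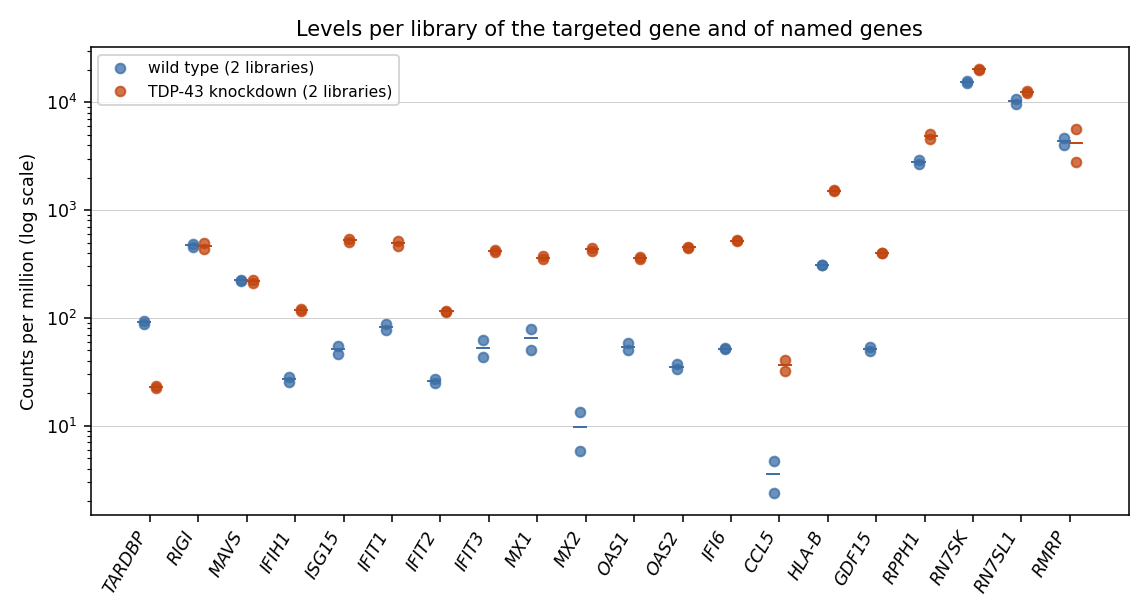
CPM on a log axis (vertical) for TARDBP and other named genes (horizontal), 1 point per library, wild type in blue and TDP-43 knockdown in orange, with a line at each group mean. TARDBP lies at 91.0 CPM in wild type and 22.8 in knockdown, the points of RIGI and MAVS overlap between groups, and those of ISG15 through GDF15 lie higher in both knockdown libraries.

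RIGI, the RNA sensor named in the title, showed no detectable difference between the groups. Its level was 473 ± 20.9 CPM in wild type and 469 ± 41.3 in knockdown (log2 fold change -0.02, 95% interval -0.17 to 0.14, edgeR adjusted p = 0.902). MAVS, the adaptor downstream of RIG-I, stood at 223 ± 3.78 and 218 ± 8.95 CPM (log2 fold change -0.03, SE 0.0786, edgeR adjusted p = 0.786). IFIH1, which encodes the sensor MDA5, rose from 27.1 ± 2.02 to 118 ± 2.89 CPM, TRIM25, a ubiquitin ligase acting on RIG-I, rose from 212 ± 13.0 to 553 ± 10.3 CPM, and DHX58, the third RIG-I-like receptor, rose from 10.4 ± 2.01 to 41.3 ± 0.0360 CPM. Among 24 tested genes of RNA sensing and signalling, 9 rose and 1 fell (9 and 1 adjusted over the list alone), IRF3 being the one that fell, though not with DESeq2, and camera gave an adjusted p of 0.0395. That call ended with adjusted p = 0.477 with an estimated correlation, and without wild-type replicate 1, wild-type replicate 2 or knockdown replicate 2 the adjusted p values were 0.0925, 0.0920 and 0.0682. Of 12 genes of cytosolic DNA sensing, 6 rose and 0 fell (6 and 0 adjusted over the list alone), SAMHD1 (1.68), TREX1 (1.79), TRIM56 (0.80) and STING1 (0.75) among them, with a camera adjusted p of 0.0788.

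Interferon transcripts themselves were close to the detection limit. IFNB1, encoding interferon beta, had no count in wild type and 4 and 2 counts in knockdown, a pooled knockdown level of 0.377 CPM, under the floor of 3 counts over the wild-type libraries (0.385 CPM). The chemokine CXCL10 had 3 wild-type and 11 knockdown counts, a ratio of 1.80 (95% counting interval 0.475 to 10.0), so no difference was detectable at this depth. CCL5, another chemokine, rose from 3.56 ± 1.69 to 36.6 ± 6.15 CPM, LIF, a cytokine of the interleukin 6 family, rose from 41.8 ± 5.35 to 174 ± 12.7 CPM, and CSF1, a macrophage growth factor, rose from 83.8 ± 1.31 to 176 ± 5.22 CPM. Of 11 tested cytokines and chemokines, 7 rose and 1 fell (7 and 1 adjusted over the list alone), CX3CL1 being the one that fell. camera's adjusted p was 0.00362, and adjusted p = 0.462 with an estimated correlation. In the list of interferons and receptors only 8 receptors and kinases could be tested and no interferon, and of these 1 rose and 3 fell (1 and 3 adjusted over the list alone), with IFNLR1 at 1.87, IFNAR1 at -0.58 and JAK1 at -0.27, and camera's adjusted p was 0.536. None of these falls was called with DESeq2 or without knockdown replicate 2. NF-kB target genes rose in 11 of 20 cases and 2 fell, BCL3 and NFKB1 (11 and 2 adjusted over the list alone), led by NFKB2 (1.35), EHD1 (0.78), TRAF1 (2.63) and IER3 (1.11). camera gave an adjusted p of 0.0214, adjusted p = 0.477 with an estimated correlation and 0.0676 without wild-type replicate 1. MHC class I antigen presentation rose in 18 of 19 genes and none fell (18 and 0 adjusted over the list alone), and TAPBP did not pass. HLA-B rose from 309 ± 1.36 to 1516 ± 30.2 CPM, TAP1, a subunit of the peptide transporter, rose from 79.9 ± 2.72 to 443 ± 13.3 CPM, and NLRC5, a transactivator of these genes, rose from 114 ± 8.23 to 576 ± 12.01 CPM. For this list camera gave an adjusted p of 1.98e-10, and adjusted p = 0.462 with an estimated correlation. HLA genes are highly similar, so their split of reads is uncertain.

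**Figure D2:**
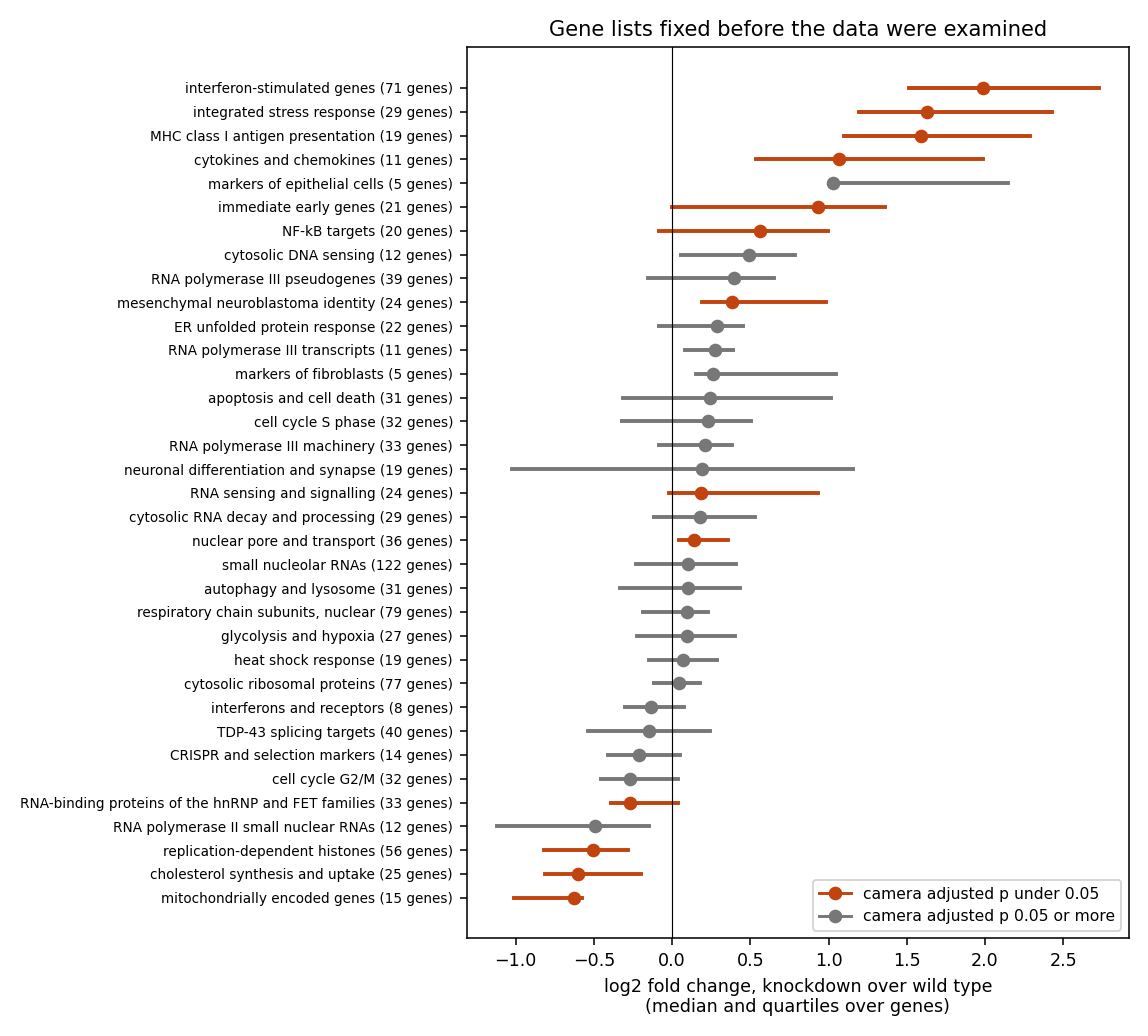
Median log2 fold change (points) and quartiles over genes (lines) on the horizontal axis for all but 1 of the 36 tested gene lists on the vertical axis, with the number of tested genes in parentheses. Orange lists had a camera adjusted p under 0.05 and grey lists did not. Interferon-stimulated genes lie at the top with a median of 1.99 and mitochondrially encoded genes at the bottom with -0.63.

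RNA polymerase III transcripts, a class of short structured RNAs, did not pass the list test as a group. RPPH1, the RNA of ribonuclease P, rose from 2785 ± 183 to 4836 ± 396 CPM, and RN7SL3, a signal recognition particle RNA, rose from 4078 ± 497 to 5867 ± 198 CPM. RN7SK, a regulator of transcription elongation, rose from 15388 ± 478 to 20165 ± 459.5 CPM (log2 fold change 0.39, SE 0.0883), and RN7SL1 rose with log2 fold change 0.28, SE 0.0886. RMRP stood at 4334 ± 419.9 CPM in wild type and 4225 ± 1996 in knockdown, where its counts were 43743 and 22972 (edgeR adjusted p = 0.969). RNY1 and VTRNA1-1 had 3 and 1 counts over the 4 libraries, below the limit of detection. Of 11 tested members, 5 rose and 2 fell (5 and 2 adjusted over the list alone), 5 and 1 with DESeq2, RNU6ATAC (-1.36) and RNA5-8SN1 being those that fell. The median was 0.28 and the mean -0.06, and camera's adjusted p was 0.506. The list passed with limma-voom, and its direction turned down in the 1.5-fold test and in some fits without 1 library. The list had taken in 5.8S ribosomal RNA genes, which RNA polymerase I transcribes, and without these 3 tested genes 5 of 8 rose and 1 fell (adjusted p 0.315). Short and highly similar RNAs are captured and counted unevenly in such libraries, and RN7SK and RMRP share their counts with a second row of the table. Among RNA polymerase III pseudogenes, 7 rose and 1 fell (6 and 1 adjusted over the list alone) of 39, 2 and 1 with DESeq2 and 12 and 2 with limma-voom, with RN7SKP71 at 0.61, and camera's adjusted p was 0.105. Subunits and factors of the polymerase itself gave 5 rises and 3 falls among 33 genes (4 and 2 adjusted over the list alone, 1 and 1 with DESeq2), POLR3C at 0.75 and GTF3C2 at -0.42 (adjusted p 0.306). For small nucleolar RNAs, 4 rose and 3 fell (1 and 0 adjusted over the list alone) of 122 (adjusted p 0.787; 1 and 0 with DESeq2, 8 and 4 with the replicate block), and for RNA polymerase II small nuclear RNAs, 0 rose and 3 fell (0 and 2 adjusted over the list alone) of 12, RNU4-2 at -1.17 (adjusted p 0.230). In cytosolic RNA decay and processing 12 of 29 genes rose and none fell (12 and 0 adjusted over the list alone), PNPT1 at 1.81, XRN1 at 0.71 and SMG1 at 0.42 (adjusted p 0.105).

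Genes whose splicing depends on TDP-43 in other work changed in both directions. SORT1, encoding the receptor sortilin, fell from 68.5 ± 3.58 to 15.9 ± 1.19 CPM (log2 fold change -2.12, SE 0.147), and TNIK, a kinase, fell from 127 ± 0.532 to 64.2 ± 4.34 CPM. SYNE1, a nuclear envelope protein, rose from 85.7 ± 1.19 to 162 ± 6.29 CPM, and MEF2D, a transcription factor, rose from 76.3 ± 3.35 to 146 ± 9.57 CPM. STMN2 had no count in any library and UNC13A had 5 wild-type and 18 knockdown counts, a ratio of 1.76 (95% counting interval 0.631 to 6.08). Of 40 tested targets, 7 rose and 16 fell (8 and 16 adjusted over the list alone). camera's adjusted p was 0.258. Gene counts carry no splicing, which was not analysed here. RNA-binding proteins of the hnRNP and FET families fell in 18 of 33 cases and 2 rose, EWSR1 and PTBP1 (3 and 18 adjusted over the list alone), with HNRNPA0 at -0.64, HNRNPUL1 at -0.43 and HNRNPH2 at -0.90. The camera adjusted p was 0.0214, adjusted p = 0.462 with an estimated correlation, and 0.0638 and 0.0526 without knockdown replicates 1 and 2. In nuclear pore and transport 11 rose and 2 fell (11 and 2 adjusted over the list alone) of 36, 6 and 1 with DESeq2, XPOT, the exporter of transfer RNA, at 1.35 and RANGAP1 at 0.80, while XPO1 and POM121 fell. There camera's adjusted p was 0.0395, adjusted p = 0.462 with an estimated correlation, and between 0.0526 and 0.104 when any 1 of the 4 libraries was left out.

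The integrated stress response, the programme of ATF4 and related factors, rose broadly. GDF15, a stress-induced cytokine, rose from 51.8 ± 2.87 to 401 ± 2.80 CPM (log2 fold change 2.97, SE 0.0913), and SESN2, a leucine sensor, rose from 34.2 ± 5.08 to 191 ± 0.439 CPM. TRIB3, a pseudokinase, rose from 101.0 ± 1.27 to 358 ± 0.0886 CPM, and WARS1, the tryptophan tRNA synthetase, which interferon also induces, rose from 51.3 ± 1.65 to 270.4 ± 13.2 CPM. Of 29 genes, 26 rose and 1 fell (26 and 1 adjusted over the list alone), with VLDLR as the one that fell, though not with DESeq2, and the median was 1.63. camera gave an adjusted p of 1.71e-12, and adjusted p = 0.401 with an estimated correlation. In the unfolded protein response of the endoplasmic reticulum, 8 rose and 2 fell (8 and 2 adjusted over the list alone) of 22, with HSPA5 at 1.48, XBP1 at 1.02 and CREB3L2 at -1.30 (camera adjusted p 0.114). Of 19 heat shock genes 6 rose and 5 fell (6 and 5 adjusted over the list alone), HSPA1B at 0.87 (adjusted p 0.536), and no fall was called with DESeq2, without wild-type replicate 2 or without knockdown replicate 1. Immediate early genes gave 13 rises and 3 falls among 21 (14 and 4 adjusted over the list alone), with DUSP5 at 2.82, FOSL1 at 2.30 and JUN at 1.10, and with EGR1, JUND and EGR2 as those that fell, EGR1 at -1.98. camera gave them an adjusted p of 0.0103, and adjusted p = 0.498 with an estimated correlation.

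Cell death genes moved both ways. MLKL, the effector of necroptosis, rose from 23.3 ± 4.55 to 76.8 ± 1.68 CPM, BAK1, a pore-forming protein of apoptosis, rose from 24.4 ± 3.91 to 68.1 ± 0.944 CPM, and BCL2, which opposes apoptosis, fell from 35.9 ± 6.01 to 7.01 ± 1.35 CPM. Of 31 apoptosis and cell death genes, 14 rose and 8 fell (15 and 8 adjusted over the list alone), 9 and 5 with DESeq2, and camera's adjusted p was 0.230. A list of genes that respond to CRISPR editing or selection had 1 that rose, FANCD2, and 5 that fell of 14 (1 and 5 adjusted over the list alone), XRCC5 at -0.69 and PRKDC at -0.43 (adjusted p 0.206). DESeq2 called 0 rises and 3 falls there. Among autophagy and lysosome genes, 12 rose and 7 fell (12 and 7 adjusted over the list alone) of 31, 7 and 5 with DESeq2, with OPTN at 1.04, SQSTM1 at 0.78 and GABARAPL1 at -1.60 (adjusted p 0.569).

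Replication-dependent histone genes, cholesterol synthesis genes and mitochondrially encoded genes were lower in knockdown. H1-5 fell from 279 ± 3.95 to 144 ± 0.192 CPM and H4C2 from 127 ± 0.334 to 55.7 ± 2.70 CPM. Of 56 histone genes, 39 fell and 1 rose, H2AC20 (2 and 39 adjusted over the list alone), with a median of -0.51, a camera adjusted p of 1.43e-07 and adjusted p = 0.462 with an estimated correlation. LSS, the lanosterol synthase, fell from 266 ± 14.2 to 119.6 ± 0.0994 CPM, HMGCS1 fell from 108 ± 13.8 to 51.3 ± 0.765 CPM and DHCR7, which completes cholesterol synthesis, fell from 150.5 ± 7.50 to 82.0 ± 0.977 CPM. In cholesterol synthesis and uptake, 0 rose and 15 fell (0 and 15 adjusted over the list alone) of 25, with a median of -0.60, a camera adjusted p of 3.13e-05 and adjusted p = 0.477 with an estimated correlation. MT-ATP8 fell from 2603 ± 309 to 1060.3 ± 37.3 CPM, and 12 of 15 mitochondrially encoded genes fell and none rose (0 and 14 adjusted over the list alone), with a camera adjusted p of 3.34e-05 and adjusted p = 0.578 with an estimated correlation. Mitochondrial transcripts made up 16.8% and 12.3% of counts in the wild-type libraries and 7.80% and 7.89% in the knockdown libraries. The largest share stood in the library with the fewest counts. Mitochondrial ribosomal RNA alone made up 8.59% and 4.97% of counts in wild type and 2.73% and 2.83% in knockdown. Its genes MT-RNR1 and MT-RNR2 did not pass (edgeR adjusted p = 0.166 and 0.0624). Uneven depletion of ribosomal RNA was not tested. In a list of nuclear-encoded respiratory chain subunits that had taken in 4 tested pseudogenes, 3 rose and 8 fell (1 and 3 adjusted over the list alone) of 79, ATP5PB at -0.75 (adjusted p 0.779), and without the pseudogenes 3 rose and 8 fell of 75 (adjusted p 0.787). Of the 79, DESeq2 called 0 rises and 3 falls, and the replicate block 6 and 7. In cytosolic ribosomal proteins, 12 rose and 10 fell (10 and 8 adjusted over the list alone) of 77, 6 and 4 with DESeq2, RPLP0 at -0.45 and RPL36 at 0.55 (adjusted p 0.716). Cell cycle genes of S phase had 9 rises and 6 falls of 32 (10 and 6 adjusted over the list alone), CDC6 at 0.78 (adjusted p 0.465), and those of G2/M had 3 and 12 of 32 (4 and 12 adjusted over the list alone), KIF20A at -1.98 and BUB1 at 0.81 (adjusted p 0.114). In glycolysis and hypoxia 9 rose and 6 fell (10 and 6 adjusted over the list alone) of 27, VEGFA, the vascular growth factor, at 2.04 and SLC2A3 at 1.40 (adjusted p 0.506).

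Most genes that mark sympathetic neuroblasts had few or no counts in the libraries labelled SH-SY5Y. Of 29 genes of adrenergic neuroblast identity, 23 had no count in any of the 4 libraries, among them PHOX2A, HAND2, ISL1, MYCN, TH, DBH and CHGA. A count of 0 over the 23690852 counts of all libraries allows up to 0.127 CPM. DDC fell from 16.3 ± 7.44 to 2.58 ± 0.536 CPM and KLF7 rose from 24.6 ± 8.52 to 70.0 ± 8.01 CPM, and the other 2 tested genes, GATA2 and TBX2, did not pass, so the list was too small for a list test. Of 31 genes of mesenchymal neuroblastoma identity, 24 had counts and were tested, and 15 rose and 2 fell (15 and 2 adjusted over the list alone), SPARC and FN1 being those that fell. CD44, a hyaluronan receptor, rose from 64.4 ± 11.99 to 546 ± 37.5 CPM, FOSL1 from 109 ± 20.8 to 518 ± 21.1 CPM, CCN1 from 115 ± 1.23 to 334 ± 2.28 CPM and IRF1, an interferon-regulated factor, from 44.5 ± 5.51 to 191 ± 7.85 CPM. camera gave this list an adjusted p of 0.00106, and adjusted p = 0.462 with an estimated correlation. FOSL1 was also a member of the immediate early list and IRF1 of the MHC class I list, so these list results are not independent. Of 19 tested genes of neuronal differentiation and synapse, 6 rose and 6 fell (7 and 6 adjusted over the list alone), with NEFL at -1.81, TUBB3 at -1.18, STX1A at 2.20 and ANK2 at 1.54 (adjusted p 0.787), the median being 0.19 and the mean -0.03. Of 14 epithelial markers 9 were not tested, with at most 17 counts each over the 4 libraries, and of the 5 tested 4 rose and 1 fell (4 and 1 adjusted over the list alone). KRT8 rose from 217 ± 2.61 to 444 ± 15.9 CPM, KRT18 from 87.5 ± 0.587 to 177 ± 1.14 CPM and CLDN4 from 20.6 ± 1.46 to 97.1 ± 0.349 CPM, whereas ELF3 fell from 39.2 ± 3.96 to 15.1 ± 0.183 CPM (camera adjusted p 0.0964 for the list). Of 5 tested fibroblast markers on a list of 14, COL6A3 (1.76) rose and LUM (-2.01) fell, also when adjusted over the list alone (adjusted p 0.410), while the glial markers MBP (1.11) and PMP22 (0.86) and the blood markers CD68 (2.68) and LAPTM5 (1.71), each pair the tested members of a list of 14, rose. PMP22 and LAPTM5 did not pass with DESeq2, nor LAPTM5, with 7 wild-type counts, with the replicate block. A panel of kidney lineage genes, added after PAX8 and CDH6 had been seen, held 7 of 10 genes at 10 CPM or more in both wild-type libraries. PAX8, a transcription factor of kidney and thyroid development, fell from 606 ± 28.7 to 524 ± 0.183 CPM, PAX2 fell from 168 ± 17.4 to 61.1 ± 1.12 CPM and CDH16, a kidney cadherin, fell from 65.8 ± 4.15 to 7.86 ± 0.725 CPM.

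**Figure D3:**
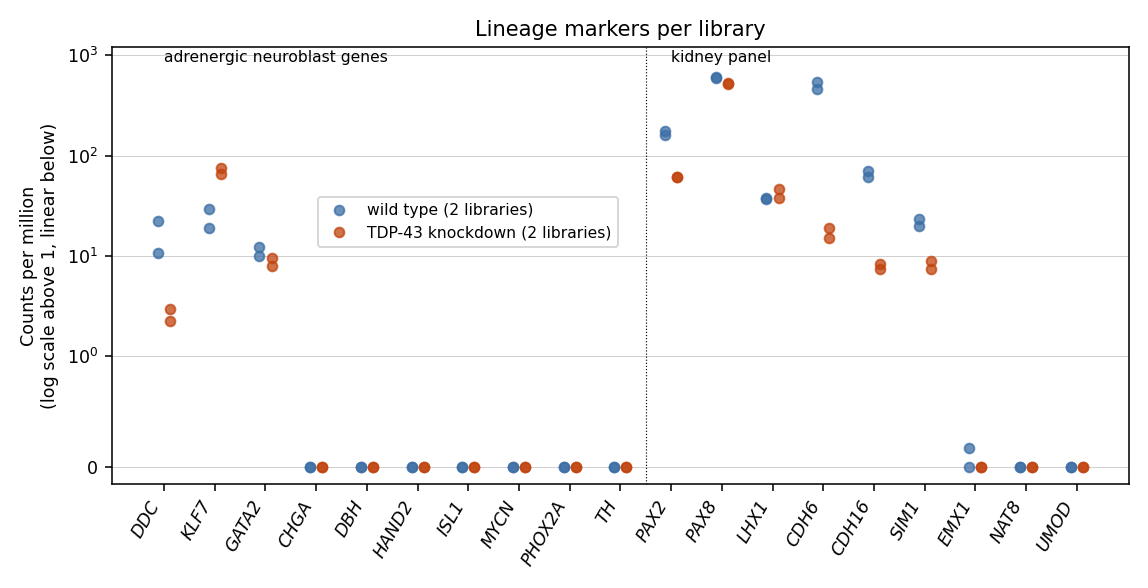
CPM per library (vertical, log scale above 1 and linear below) for some genes of adrenergic neuroblasts, left, and of the kidney panel, right, with wild type in blue and TDP-43 knockdown in orange. HAND2, ISL1 and TH lie at 0 in all 4 libraries, and PAX8 lies above 500 CPM in each.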

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

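IFNL1, encoding an interferon lambda, stood out as a signal in a gene that the count filter had left out of the comparison. It had no count in wild type and 5 and 6 counts in the knockdown libraries, 11 together or 0.692 CPM. The wild-type libraries allow up to 0.385 CPM, and the pooled knockdown level was 1.80 times that limit. Counting error of the 11 knockdown counts is left out, so 1.80 is not a lower bound. Fisher's exact test on the pooled counts, which ignores the spread between libraries, gave an unadjusted p of 0.0205. No explanation was tested.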

How the results depend on the processing

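The fits without 1 library, the replicate block and the other planned settings were chosen before the data were examined, and thinning, repeated rows and corrected lists after. TARDBP fell past the threshold in every setting that kept all libraries, and its log2 fold changes ran from -2.04 to -1.95 when 1 library was left out. A fit without 1 library leaves 1 library in that group, so the other group alone gives the spread and its calls are weak evidence of stability. The number of genes called within a list, up or down, moved by over 1.5 times in 18 of 39 lists with DESeq2, 12 with no filter, 12 after thinning and 7 to 18 without 1 library, in 34 in the 1.5-fold test, and in at most 5 in each other setting. DESeq2 gave 1953 higher and 1876 lower, for which the cause was not tested, and the test against a 1.5-fold change, which is stricter by construction, 1150 and 898. Leaving out 1 library gave 2152 to 3190 higher and 1920 to 2958 lower, with fewer samples. The replicate block gave 3090 higher and 2924 lower, and the deviations of same-numbered libraries correlated at 0.0325, so the numbers do not establish pairing. Thinned to the depth of wild-type replicate 1, 2241 rose and 2187 fell, with 12397 genes tested. Of 172 named genes past the threshold none changed sign in any setting run, and 149 stayed past it in all except the 1.5-fold test. Apart from the fixed genes, they were named by their values in these same counts, so this is weak evidence of stability. Changing size factors moved no list across the threshold.

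Interferon-stimulated genes kept an adjusted p under 0.05 in all settings with every library except the estimated correlation (0.401). Their direction stayed up in each fit without 1 library, where the spread comes from the other group alone. TDP-43 splicing targets did not pass with camera in any setting (0.228 to 0.386 without 1 library) nor with fry as a list moving in 1 direction (0.0594). RNA polymerase III transcripts passed with limma-voom (0.0327), turned down in the 1.5-fold test (0.934), and ran from 0.206 to 0.666 without 1 library, turning down without wild-type replicate 2 (0.633) or knockdown replicate 1 (0.666), and the cause was not tested. Lists far from the threshold also changed sign, in each case without passing: interferons and receptors with no filter (0.896) and in the 1.5-fold test (0.934), 1 further list with DESeq2 (0.673), in the 1.5-fold test (0.959) and with fry (0.315), ribosomal proteins in the 1.5-fold test (0.934), autophagy and lysosome likewise (0.936), respiratory chain subunits with DESeq2 (0.989) and in the 1.5-fold test (0.934), and neuronal genes with DESeq2 (0.954), no filter (0.879), the 1.5-fold test (0.936), fry (0.808) and thinning (0.849). Without 1 library the ranges were 0.0551 to 0.930 for small nucleolar RNAs, 0.408 to 0.994 for ribosomal proteins, 0.459 to 0.847 for respiratory chain subunits and 0.414 to 0.933 for neuronal genes, each with a turn of direction in at least 1 fit. Log2 fold changes near 0 changed sign for RIGI (0.019 with no filter, -0.10 to 0.081 without 1 library), MAVS (0.00023 with no filter, 0.013 after thinning, -0.066 to 0.016 without 1 library) and RMRP (0.0037 with no filter, -0.61 to 0.39 without 1 library), and RMRP passed without knockdown replicate 1 or 2. The cause was not tested. With wild-type replicate 1 at 1962476 counts, genes under about 1.53 CPM cannot be followed in that library.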

Other observations

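The tests of identity, of depth, of RIGI, of a second control line and of the tRNA synthetases, and the removal of trends from all called genes, were chosen only after the results were seen, and those of chromosomes, of the correlation with gene length and of GC content in protein-coding genes before. Cytosolic tRNA synthetases, which load amino acids onto tRNA, were mostly higher in knockdown, 14 of 20 rising and 1, QARS1, falling, with the same counts when adjusted over the list alone. MARS1 rose from 63.6 ± 7.14 to 272 ± 2.88 CPM, AARS1 from 158 ± 9.72 to 454 ± 13.5 CPM and YARS1 from 62.4 ± 12.8 to 219 ± 7.08 CPM. Of 17 mitochondrial synthetases, 5 rose and 2 fell, with CARS2 at 1.41 and HARS2 at -0.63. The medians were 0.61 for cytosolic and 0.14 for mitochondrial enzymes, a difference of 0.46. The hypothesis that the classes differ was not borne out at 0.05, since 100000 reassignments of genes gave a permutation p of 0.0583 (two-sided, across genes, which are not independent).

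Genes of the protocadherin beta cluster, neighbouring cell surface proteins on chromosome 5, were lower in knockdown. Of 10 tested, 8 fell and none rose (9 adjusted over the list alone), with a median of -1.89. PCDHB13 fell from 18.5 ± 1.52 to 4.81 ± 1.16 CPM and PCDHB14 fell from 13.6 ± 1.62 to 3.94 ± 1.01 CPM.

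The lack of counts for most adrenergic neuroblast genes in libraries labelled SH-SY5Y has a technical side. Depth cannot account for it, since a count of 0 over the 4 libraries allows 0.127 CPM at most. A candidate explanation is cells of another lineage than the label names, by mix-up or mislabelling: HAND2 and ISL1 had no count, and 7 of 10 kidney genes stood at 10 CPM or more in both wild-type libraries, 5 of 8 without PAX8 and CDH6, which had prompted the panel, against at most 1 gene in each of the 9 other, smaller tissue panels. A mesenchymal state of the same line could not be decided. Its prediction asked for PRRX1, TWIST1, MEOX1 and MEOX2 above 1 CPM, and not all of these were. Counts in 24 of 31 mesenchymal genes do not tell such a state from another lineage. No biological explanation other than that state was tested, and PAX8 was high in both groups.

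The breadth of the change, 6019 genes, was weighed against technical differences. Unequal depth as the whole cause is argued against, since 35.7% of the genes tested after thinning to equal depth were called, against 37.7% at full depth, with 4212 of the 6019 called again. It stays open for 602 called genes that had too few counts to be tested after thinning. Direction after thinning, measured first, is close to fixed for genes called in the same counts and decides nothing. Whole-chromosome gain or loss shared by all cells is argued against, since the chromosome median farthest from that of all genes was -0.13 (log2, chromosome 13). Small shifts, from -0.134 to 0.117, had a permutation adjusted p under 0.05 for chromosomes 2, 4, 6, 13, 17, 19, 22 and X. That permutation treats genes as independent. Gain or loss in part of a chromosome or in part of the cells was not tested. Long genes fell more often than short ones, 33.3% against 16.9% in the longest and shortest quintile of protein-coding genes with a mean of at least 5 CPM, with medians of -0.149 and 0.0879 (Spearman rho -0.141 across genes). Gene length as the whole cause is argued against by the small size of this trend. After its removal, 99.1% of 5986 called genes with annotation kept their sign and more than 0.5 of their size. So small a trend can hardly alter genes already called in the same counts, so that share adds no support. What makes the trend was not tested. The trend with GC content was also small, with a Spearman rho of 0.177 across the same genes, which argues against GC content as the whole cause. After its removal 99.6% of 4810 called protein-coding genes with a mean of at least 5 CPM were kept, and 99.5% of the 5986. For the same reason these shares add no support. Loss of TDP-43 and a difference between 2 cell populations unrelated to it cannot be told apart, because the labels name 0 further control lines or knockdown populations. The falls of kidney lineage genes such as PAX2 are part of this open question.

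RIGI showed no detectable difference while most interferon-stimulated genes rose. A ceiling for abundant genes is argued against, since 85.7% of the 21 interferon-stimulated and MHC class I genes at 100 CPM or more in wild type rose. Interferon activity already high in wild-type cells stays open. In wild type 5 of the 71 genes lay at or above RIGI's level, which few genes of any kind reach, and the median of the list was 48.0 CPM against 16.6 for all tested genes. RIGI ranked at place 168 of all tested genes in wild type, and whether RIGI carries a further source of expression in these cells was not tested.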
